A study of Mus musculus with 8 samples.

How the data were processed

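Total RNA from sorted mouse CD4+ T cells was profiled on Agilent mouse miRNA arrays, with 2 arrays for each of 4 groups (vector or Bcl-6 retrovirus, GFP-negative or GFP-positive), per the labels. Each scanner file holds 1 array in 1 colour. Spot intensities, the deposited values used here, had been background-subtracted and spatially detrended with Agilent Feature Extraction 10.1.1.1, per the file headers, and no step between arrays is recorded there. They are on a linear scale and can be negative. The deposited series table is also an intensity on a linear scale, uncentred, and equalled the total signal per miRNA in the scanner files (largest difference 0 over 599 entries); its column medians ran from -35.7 to 7.34. The labels name miRBase release 9.2 for the array, and miRNA names are kept as the files give them.

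All 8 arrays came from 1 slide and 1 scan, so no batch could be fitted. The vector arrays lay on row 1 of the slide and the Bcl-6 arrays on row 2, so that slide row and retrovirus cannot be told apart within a sorted fraction. The GFP-negative arrays lay in columns 1 and 2 and the GFP-positive arrays in columns 3 and 4, so that slide column and sort cannot be told apart within a culture. Each group thus had its own part of the slide, and an effect of that part cannot be told apart from the group. The files listed 12493 spots per array, with 5 to 20 spots per probe, 1672 mouse probes and up to 4 probes per miRNA. At most 26.1% of mouse probes were well above background on an array, and 0 spots were saturated. Signal over background on each array, not a read depth, set what could be measured.

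Spots marked as outliers and control spots were left out, and the processed signals of the spots of a probe were averaged. A probe counted as well above background where over 50% of its spots were. Signals were divided by the array's 75th percentile over the 154 mouse probes well above background on all arrays, then raised to a common floor (-5.37 on the log2 scale, the median over arrays of the lowest scaled signal well above background), then put on the log2 scale. Each miRNA was represented by the probe with the highest mean over all arrays. A miRNA was called below background only if all its probes were, and was tested where it was well above background on both arrays of at least 1 group. Viral probes stayed out of the tests. All log2 differences are on this floored scale, which can understate the change of a miRNA that lies at the floor. It can also overstate rises of dim miRNAs on dim arrays. On the Bcl-6 GFP-positive arrays the lowest scaled signals well above background were -4.31 and -4.44, so that signal not above background there can exceed the floor. Coordinates from the array were not used here, because the array was designed on another genome build than the gene table at hand. The gene table served only for names and, by its own coordinates, for which miRNA genes lie within 10 kb of each other.

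Comparisons were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, all 8 arrays in 1 model with a mean per group and no block, two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. The residual degrees of freedom were 4 and the prior added 2.43. Lists of miRNAs (22 lists, 13 with at least 3 tested members) were tested with camera, with a preset correlation of 0.01 and with an estimated one, and with fry. The lists covered the miR-17-92, miR-106a-363, miR-106b-25, miR-23/27/24, Dlk1-Dio3 and Sfmbt2 clusters, the embryonic cluster of miR-290 to miR-295, the let-7, miR-15/16, miR-26 and miR-30, miR-29 and miR-181 families, miRNAs induced by T cell activation or abundant in naive T cells, and red cell, myeloid, stromal, endothelial, epithelial, liver, muscle and neural markers. Of their 177 names, which include older spellings, 162 matched a miRNA on the array.

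The miRNAs named in the text were set by a rule. For Bcl-6 against vector in GFP-positive cells these were the 10 largest rises and 10 largest falls among miRNAs past the threshold, well above background on both arrays of the higher group and with both arrays of one group above both of the other. Chance alone separates 2 arrays from 2 for 33.3% of miRNAs. All measured members of the miR-17-92, miR-106a-363 and miR-106b-25 lists were added, and always miR-155, miR-150, miR-146a, miR-21, miR-16, let-7a, miR-142-3p, miR-223 and miR-181a. For the other comparisons the 5 largest rises and falls were taken, for the other lists the 2 to 4 members with the largest moderated statistic, and for markers of other cells and viral probes those well above background on both arrays of a group. The comparisons, tests, lists and this rule were fixed before the data were examined.

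Alternatives covered the background correction (normexp with offset 50), the scaling, the filter on dim miRNAs, the probe summary, the floor, the arrays in the fit, the replicate number as a block, the moderation, a 1.5-fold minimum, the deposited table, the arrays of a group averaged and each array left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Mean spot signals, which the normexp alternative was planned on, are not among the columns of these files, and median spot signals were used in their place. The fit was tested on simulated data built from the real means and residual spread of the 197 miRNAs, for Bcl-6 against vector in GFP-positive cells. Of 20 miRNAs planted per size it recovered 8 at 1.5-fold, 14 at 2-fold and 19 at 3-fold, and it called 2 of 137 unchanged miRNAs. In a simulated comparison without change it called 0 of 197. In a simulated list test 1 of 1 lowered list and 0 of 12 unchanged lists passed. The simulated noise was independent between miRNAs, with no floor and no dimmer or uneven array, while estimated correlations within the real lists reached 0.68. The simulations therefore do not show how often miRNAs or lists are called falsely in these data.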

Results

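Naive CD4+ T cells from mice were transduced with a retrovirus expressing Bcl-6, the transcriptional repressor that directs follicular helper T cells, or with the control vector. They were grown for 2 days without polarising cytokines and sorted by GFP, the marker carried by the retrovirus. MicroRNA levels were then measured on 1-colour Agilent arrays, with 2 arrays for each of the 4 groups: vector GFP-negative, vector GFP-positive, Bcl-6 GFP-negative and Bcl-6 GFP-positive. The arrays listed 567 mouse miRNAs. Between 177 and 203 of them were well above background on the 4 vector arrays, 207 on repeat 2 of Bcl-6 GFP-negative cells, and 145 and 157 on the Bcl-6 GFP-positive arrays. Repeat 1 of Bcl-6 GFP-negative cells stood apart, with 84 such miRNAs and 73.3% of its spots negative after background subtraction, against 29.4% to 39.5% on the other arrays. A total of 197 miRNAs were tested and 79 were well above background on all 8 arrays. The series states that each sample was run in duplicate, and nothing says that the 2 arrays of a group came from separate cultures. The p-values therefore measure the spread between arrays, which may be technical, and compare these RNA samples rather than the conditions. Where both arrays of a group lay at the floor, their SD was 0 by construction, so that the SE and p-value understate the spread. Examples are miR-222 in both vector groups, miR-451 and miR-762 in both GFP-negative groups, and miR-363 in Bcl-6 GFP-positive cells. The number of arrays limits the precision.

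The first comparison asked which miRNAs differ in sorted cells that carry Bcl-6. The largest rises in GFP-positive cells were those of miR-222 and miR-221, a pair encoded together that restrains cell cycle inhibitors. Neither was well above background on any vector GFP-positive array, and both were on both Bcl-6 GFP-positive arrays. On the scaled signals miR-222 was thus at least 5.78-fold higher (adjusted p = 3.63e-05) and miR-221 at least 5.73-fold higher (adjusted p = 0.000235). For such a bound, the bright group's mean is set against the lowest signal measurable on the dim arrays or the dim probe's own, whichever is higher. Here and below, such a bound covers the floor and not the choice of scaling, so it holds for the main scaling only. Under each alternative scaling the log2 differences of miR-222 and miR-221 were smaller. Without scaling they were 1.569 and 1.687, against 2.565 and 2.518 with the main scaling. miR-34a, a target of p53, rose by 1.89 ± 0.15 on the log2 scale (SE, n = 2 arrays per group, adjusted p = 0.000487). miR-155, which is needed for normal germinal centre responses, rose by 1.37 ± 0.14 (adjusted p = 0.00116). In the other direction, miR-21, one of the brightest miRNAs of these cells, fell by 1.12 ± 0.12 (adjusted p = 0.00116), and miR-132, a miRNA induced through CREB, fell by 1.27 ± 0.13 (adjusted p = 0.00116).

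In all, 60 of the 197 tested miRNAs differed between Bcl-6 and vector in GFP-positive cells (limma with Benjamini-Hochberg adjustment), 43 higher and 17 lower, and 54 of the 60 by at least 1.5-fold. The other large rises were those of miR-574-3p (log2 difference 1.75), miR-500 (1.64), miR-302c (1.62), miR-483* (1.61), miR-467b* (1.54), miR-466g (1.53) and miR-466f-3p (1.52), with SEs from 0.18 to 0.39 and adjusted p from 0.00116 to 0.0258. miR-302c missed the threshold without vector GFP-positive repeat 2 (adjusted p = 0.0502), and miR-500 and miR-467b* missed it without any one of the 6 arrays outside the Bcl-6 GFP-negative group (adjusted p up to 0.152 and 0.199). The largest falls included miR-363, well above background on both vector GFP-positive arrays and on neither Bcl-6 GFP-positive array and at least 1.40-fold lower (adjusted p = 0.0259). It too missed the threshold without any one of those 6 arrays (adjusted p up to 0.166). Besides miR-132 and miR-21, given above, the other large falls were those of miR-27b (log2 difference -1.19 ± 0.22), miR-23b (-0.86 ± 0.13), miR-20b (-0.73 ± 0.13), miR-106a (-0.71 ± 0.12), miR-19a (-0.65 ± 0.14), miR-27a (-0.65 ± 0.13) and miR-17 (-0.63 ± 0.12). Of the 60 miRNAs, 54 had 2 or more measured probes, and in none of those did the probes differ in sign.

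**Figure D1:**
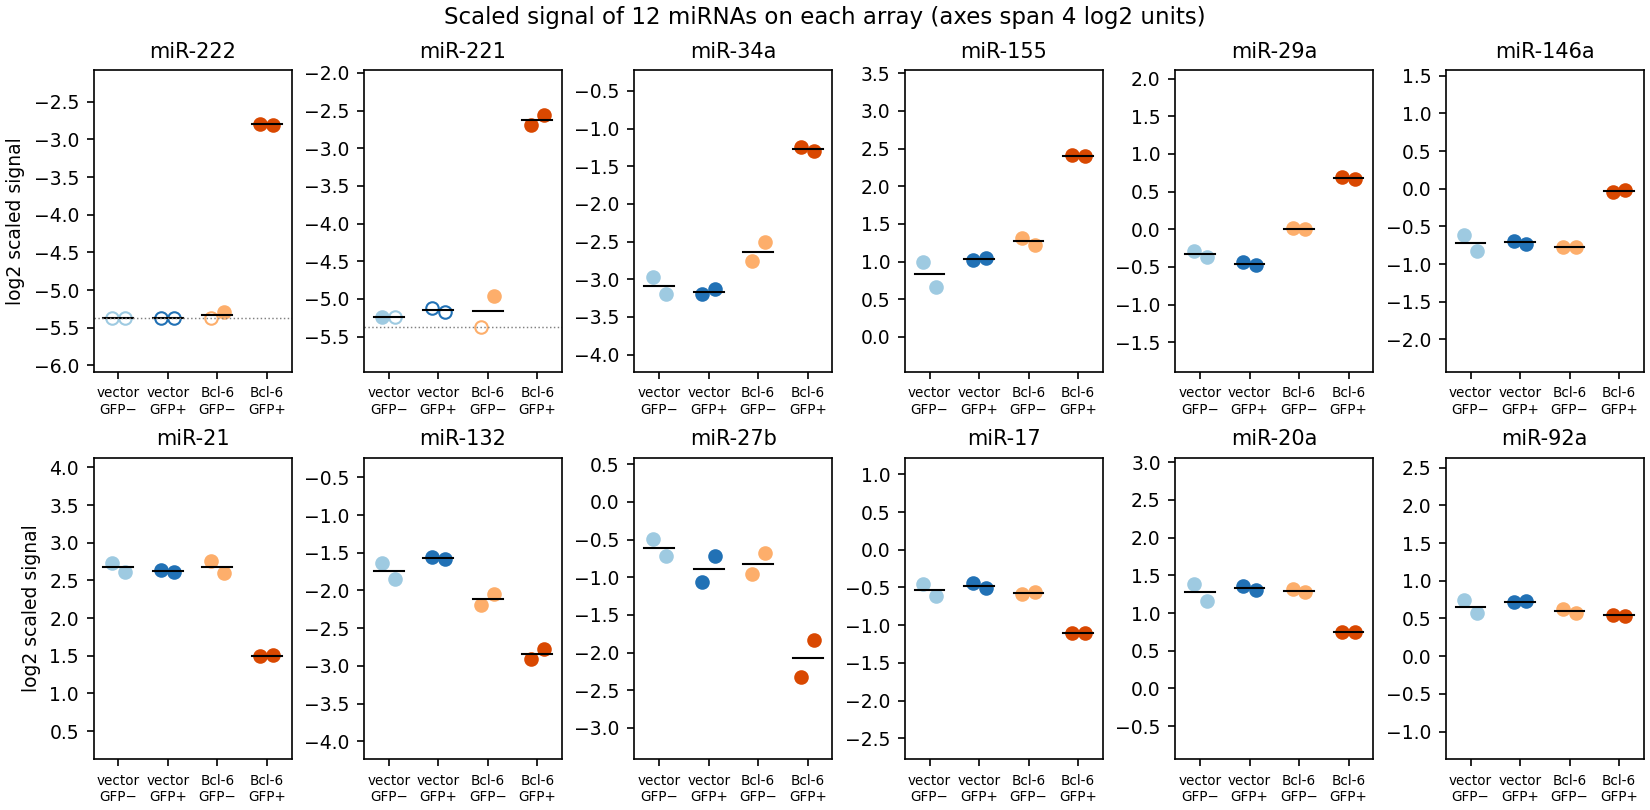
Scaled log2 signal of 12 miRNAs (vertical axis) on each of the 8 arrays, by group (horizontal axis), with points for arrays, filled where the miRNA was well above background, bars for group means and a dotted line for the floor. miR-221 and miR-222 rise from or near the floor on the Bcl-6 GFP-positive arrays and miR-21 differs from vector by -1.12 there, while the higher level of miR-146a turns to a difference of -0.15 without scaling.

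The numbers of rises and falls depended on how the arrays were brought to a common scale. The Bcl-6 GFP-positive arrays were dimmer. Their 75th percentiles were 267 and 304.3, against 496 and 518 on the vector GFP-positive arrays. Before scaling, the median difference of the 79 miRNAs seen on all arrays was -0.89 on the log2 scale, and 62 of the 79 were lower. Over 19 probes for control RNAs the median was -0.53, ranging from -0.70 to -0.25. The files do not state what these control RNAs and the corner spots are, or whether they were added per amount of RNA, so what a scaling on them holds constant is unknown. The split was 35 higher and 49 lower with quantile normalization, 5 and 50 with no scaling, 22 and 39 with scaling on the control RNAs, and 12 and 12 with scaling on the corner control spots, a setting chosen after seeing the data. These settings moved the median difference of the tested miRNAs from 0.10 by -0.31, -0.60, -0.21 and -0.25. All 17 falls kept their sign under all 5 scalings and 12 of them stayed past the threshold, among them miR-17, miR-18a, miR-19a, miR-19b, miR-20a, miR-20b, miR-21, miR-106a and miR-132. Of the 43 rises, 34 kept their sign and 5 stayed past the threshold: miR-221, miR-222, miR-34a, miR-574-3p and miR-483*. Every alternative scaling moved the median down, which favours falls over rises, so these counts do not compare how well the 2 directions hold. Normexp background correction, not among the 5, moved the median up by 0.37. It gave 143 higher and 22 lower, and miR-363 turned sign.

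The count also moved with single arrays. It was 27 without vector GFP-positive repeat 1, 32 without its repeat 2, 36 without Bcl-6 GFP-positive repeat 2, and 103 and 95 without repeat 1 or repeat 2 of Bcl-6 GFP-negative cells. Of the 60 miRNAs, 22 (19 higher, 3 lower) passed with each of the 8 arrays left out in turn, among them miR-221, miR-222, miR-34a, miR-155, miR-29a, miR-29b, miR-21, miR-132 and miR-23b, and none changed sign. The count was 33 (29 higher, 4 lower) with the deposited signal per miRNA, 165 (143 higher, 22 lower) with normexp background correction, and 108 when only these 4 arrays were fitted. With the arrays of each group averaged, the Bcl-6 GFP-positive sample was set against the 3 other samples, which are of different kinds. This is another contrast, with the spread taken among those 3 unlike samples and the lone sample assumed to vary like them. In it 2 miRNAs passed, miR-221 and miR-222 (adjusted p = 0.0151 for both).

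Groups of miRNAs were read through lists fixed before the data were examined, of which 13 had at least 3 tested members. Of the miR-17-92 cluster, which promotes lymphocyte proliferation and survival, 5 of 7 tested members fell: miR-17, miR-18a (-0.60 ± 0.12), miR-19a, miR-19b (-0.58 ± 0.13) and miR-20a (-0.59 ± 0.13). miR-92a differed by -0.18 ± 0.12 (adjusted p = 0.293) and miR-17* by -0.13 ± 0.12 (adjusted p = 0.444). Without scaling or with scaling on control RNAs all 7 were lower, and with quantile normalization 6. This cluster is known to have been singled out by the study from these samples, so the list is not independent evidence of its direction. Of the list for the related miR-106a-363 cluster 3 of 3 tested members fell, namely miR-106a, miR-20b and miR-363, while miR-18b was too dim to test. miR-19b and miR-92a also have genes within 10 kb of miR-106a but were counted with miR-17-92 only. They cannot be assigned to 1 of the clusters here, and miR-92a did not pass. Of the miR-106b-25 cluster 0 of 3 members passed, with miR-106b at -0.34 ± 0.11 (adjusted p = 0.0603), miR-93 at -0.42 ± 0.14 (adjusted p = 0.0692) and miR-25 at -0.21 ± 0.12 (adjusted p = 0.225), although all 3 were lower without scaling or with scaling on control RNAs. Of the miR-23/27/24 clusters 4 of 5 members fell: miR-23b, miR-27a, miR-27b and miR-24 (-0.44 ± 0.12, adjusted p = 0.0337). All 3 members of the miR-29 family, whose targets include DNA methyltransferases, rose: miR-29a by 1.13 ± 0.11, miR-29b by 1.00 ± 0.12 and miR-29c by 0.86 ± 0.22. The miR-23/27/24 members lower numbered 5 without scaling or with scaling on control RNAs and 3 on the corner spots, and the miR-106a-363 members lower numbered 2 under each of these. Some of these calls rested on single arrays. Without vector GFP-positive repeat 1 miR-17, miR-18a, miR-19a, miR-19b, miR-20a, miR-27a, miR-106a, miR-20b, miR-24 and miR-29c missed the threshold, with adjusted p from 0.0688 to 0.205. Without Bcl-6 GFP-positive repeat 2 the same miRNAs but miR-106a and miR-20b missed it, with adjusted p from 0.0502 to 0.139. miR-19a, miR-19b, miR-24 and miR-27b missed it without Bcl-6 GFP-positive repeat 1 (adjusted p up to 0.0945), and miR-24, miR-27b and miR-29c without vector GFP-positive repeat 2 (adjusted p up to 0.120). The tested members of these 4 families kept their signs under all 5 scalings, although no miR-29 member passed without scaling or on the corner spots, and with normexp miR-17* (0.082) and miR-363 (0.16) were above 0. Arrays can hybridise related miRNAs to the same probe, so members of one seed family may not be separate measurements, which was not tested.

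**Figure D2:**
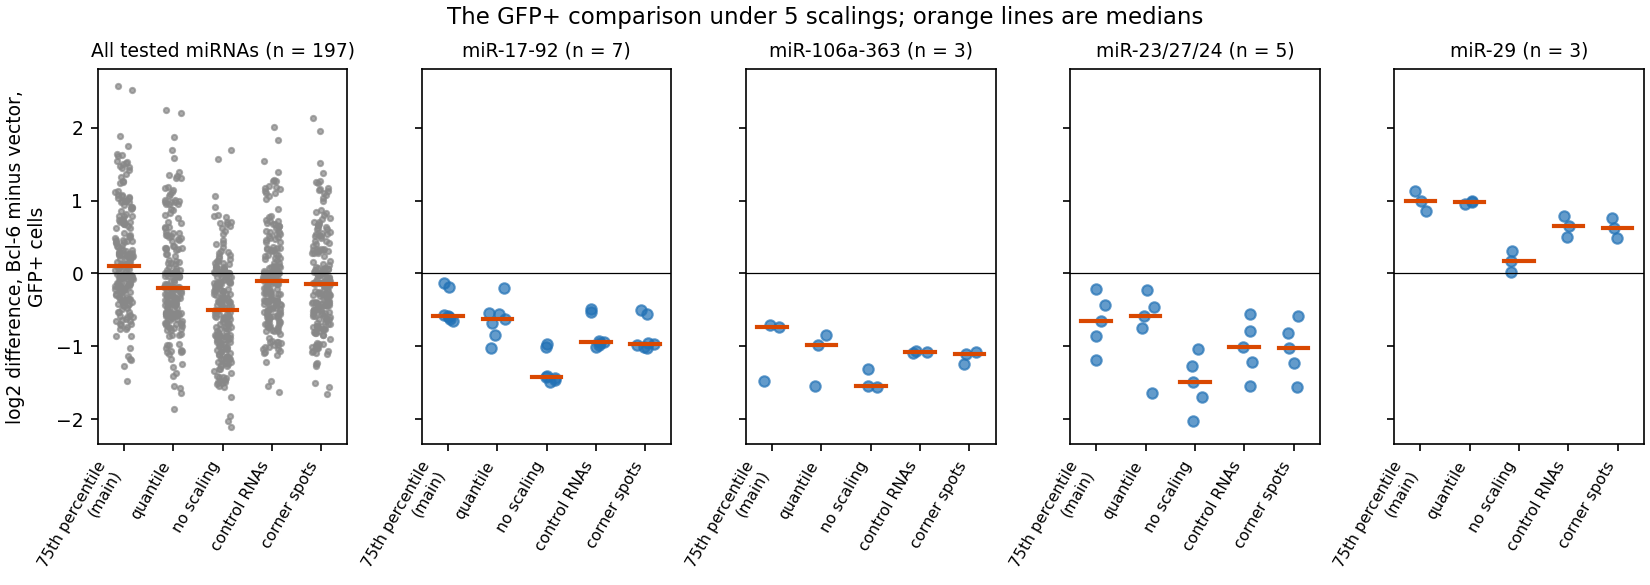
Log2 difference between Bcl-6 and vector in GFP-positive cells (vertical axis) under 5 scalings (horizontal axis), for the 197 tested miRNAs and for 4 lists; points are miRNAs and orange lines are medians. The median of all tested miRNAs runs from 0.10 with the 75th percentile to -0.50 with no scaling, while that of the miR-17-92 list runs from -0.59 to -1.42 and that of the miR-29 list from 1.00 to 0.17.

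Against the other tested miRNAs, 4 lists passed in limma's camera test with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 13 lists. These were miR-17-92 (median log2 difference -0.59, adjusted p = 0.00242), miR-23/27/24 (-0.65, adjusted p = 0.00402), miR-106a-363 (-0.73, adjusted p = 0.0151) and miR-29 (1.00, adjusted p = 0.0408). None of these calls held, each having an adjusted p = 0.484 with an estimated correlation. Over the other settings the adjusted p of these lists ran from 5.49e-08 to 0.0443 for miR-17-92, from 2.49e-07 to 0.0497 for miR-23/27/24, from 0.000648 to 0.0813 for miR-106a-363 and from 0.000156 to 0.238 for miR-29, which passed under 16 of 23 settings. In limma's fry test, which asks whether the members of a list move on balance in one direction, 6 lists passed: these 4, miR-106b-25 (adjusted p = 0.0142) and the list of miRNAs induced by T cell activation (adjusted p = 0.00415). Adjusted over the list alone, the members passing numbered 5 for miR-17-92, which again is not independent evidence, 3 for miR-106a-363, 2 for miR-106b-25, 4 for miR-23/27/24 and 3 for miR-29.

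The list of miRNAs induced by T cell activation moved in both directions. Of its 10 tested members 5 rose, among them miR-222, miR-221, miR-155 and miR-146a, a miRNA induced by NF-κB (0.68 ± 0.12, adjusted p = 0.00813), while miR-21 and miR-132 fell. The rise of miR-146a turned to -0.15 without scaling, as did that of the hypoxia-induced miR-210 (0.70 to -0.13), which was named after its values were seen. miR-146a missed the threshold without vector GFP-positive repeat 1 (adjusted p = 0.0688) or Bcl-6 GFP-positive repeat 2 (adjusted p = 0.0502), and miR-210 without the former (adjusted p = 0.0565). Without scaling 2 members of the list of miRNAs induced by T cell activation were higher and 3 lower, and its median turned from 0.68 to -0.15. With normexp 7 were higher and 2 lower. The fry test of this list was run with the 75th percentile scaling alone. In camera this list had an adjusted p = 0.238, and 7 members passed adjusted over the list alone. Of 11 miRNAs abundant in naive T cells 1 passed, miR-29a, and with no scaling or with scaling on control RNAs 6 others were lower. With normexp 5 of the 11 were higher and 3 lower. miR-150, a miRNA of resting lymphocytes, differed by 0.27 ± 0.25 (adjusted p = 0.453), a sign kept by none of the other 4 scalings, and miR-142-3p, specific to blood cells, by -0.42 ± 0.19 (adjusted p = 0.141). For this list the camera test pointed down (adjusted p = 0.322), as did the median (-0.14) and mean (-0.03), and the fry test pointed up. miR-16 differed by -0.21 ± 0.13 (adjusted p = 0.279) and let-7a by -0.25 ± 0.15 (adjusted p = 0.270). miR-181a was not well above background on any GFP-positive array, and miR-223 was not on any of the 8 arrays.

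None of the other lists passed in camera. No tested member passed among the let-7 family (8 tested, adjusted p = 0.0922 in camera), the miR-15/16 family (4 tested, 0.322), the miR-181 family (3 tested, 0.727) or the miR-26 and miR-30 families (7 tested, 0.522). With no scaling 6, 3, 1 and 3 members of these families were lower, with quantile normalization 2, 1, 0 and 4, and with scaling on control RNAs 5, 2, 0 and 2. With normexp 2, 2, 0 and 0 were lower and 3, 1, 2 and 4 higher. In the imprinted Dlk1-Dio3 cluster 2 of 9 tested members were higher, miR-376c (log2 difference 1.25) and miR-485* (1.06), and 2 passed adjusted over the list alone. These differences hold for the main scaling only. They are not lower bounds, because signal not above background on 1 Bcl-6 GFP-positive array entered the mean. Without scaling the log2 differences of miR-376c and miR-485* were 0.29 and 0.065, against 1.25 and 1.06 with it. With quantile normalization 1 member was higher, and with no scaling, on control RNAs or on the corner spots 0, while 1 was lower with no scaling. With normexp 7 were higher and 0 lower. miR-376c and miR-485* were well above background on 1 Bcl-6 GFP-positive array and no vector GFP-positive array, and both missed the threshold without any one of the 4 vector arrays (adjusted p up to 0.161). Its median was -0.01, its mean 0.26 and its camera test pointed up (adjusted p = 0.864). Among 7 tested members of the Sfmbt2 intron cluster 4 rose, including miR-669c (1.07 ± 0.18) and miR-669a (0.79 ± 0.17), and 7 passed adjusted over the list alone, not all in one direction (camera adjusted p = 0.417). With quantile normalization 2 of its members were higher and 2 lower, with scaling on control RNAs 1 and 1, with no scaling 0 and 1, and on the corner spots 0 and 0. With normexp 6 were higher and 0 lower. Without scaling miR-669a was at -0.046, and miR-297a, another of the 4, at -0.12. The calls of miR-297a and miR-466a-5p, the rest of the 4, each held in 2 of 8 fits that left out 1 array. miR-669c missed the threshold without vector GFP-positive repeat 2 (adjusted p = 0.0621), and miR-669a without either vector GFP-positive array or Bcl-6 GFP-positive repeat 1 (adjusted p up to 0.124). Of 10 listed miRNAs of the embryonic cluster from miR-290 to miR-295, 2 were tested, miR-290-5p and miR-294, and 0 passed. miR-295*, an opposite strand that is not on the list, was also tested and did not pass (-0.02 ± 0.17, adjusted p = 0.938).

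Markers of other cell types were mostly below background. None of the myeloid, stromal, endothelial, epithelial or liver markers was well above background on any array. Of the muscle and neural markers, those tested did not pass, miR-206 (0.91 ± 0.44, adjusted p = 0.155) and miR-128 (0.27 ± 0.16, adjusted p = 0.254). The red cell miRNA miR-451 was higher in Bcl-6 than in vector GFP-positive cells by 1.24 ± 0.12 (adjusted p = 0.00116) and was not well above background on any GFP-negative array, while the other 2 red cell markers on the array were below background throughout.

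In GFP-negative cells of the same cultures, sorted as lacking the retroviral marker, 0 of 197 miRNAs passed in limma for Bcl-6 against vector. At an unadjusted p under 0.05 there were 56, and the smallest adjusted p was 0.134. miR-21 differed by 0.00 ± 0.12, miR-17 by -0.04 ± 0.12, miR-29a by 0.34 ± 0.11 (adjusted p = 0.142), miR-155 by 0.43 ± 0.14 (adjusted p = 0.144) and miR-34a by 0.45 ± 0.15 (adjusted p = 0.142). miR-222 was well above background on 1 of the 4 GFP-negative arrays. In camera 2 lists passed, miR-29 (median 0.38, adjusted p = 0.000605) and miR-181 (median 0.81, adjusted p = 0.0271), both upward relative to the other miRNAs. That reference lay below 0, with a median of -0.25 over all tested miRNAs, and the 118 miRNAs not seen on all arrays had a median difference of -0.58 between repeat 1 and repeat 2 of Bcl-6 GFP-negative cells. Neither list passed with an estimated correlation (adjusted p = 0.279 with an estimated correlation for both). No member of either list passed singly, and 2 of each passed adjusted over the list alone. The count was 91 without repeat 2 of Bcl-6 GFP-negative cells, where repeat 1 with its uneven background was the only array of its group, and 0 without that repeat 1. It was 7 without vector GFP-negative repeat 1, 1 without its repeat 2, and from 0 to 6 under the other settings. Across the 197 miRNAs, which are not independent replicates, the differences in GFP-positive and GFP-negative cells, which share no array, had Pearson's r = 0.158 and Spearman's rho = 0.0844, and across the 79 seen on all arrays r = 0.0769 and rho = -0.0446.

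**Figure D3:**
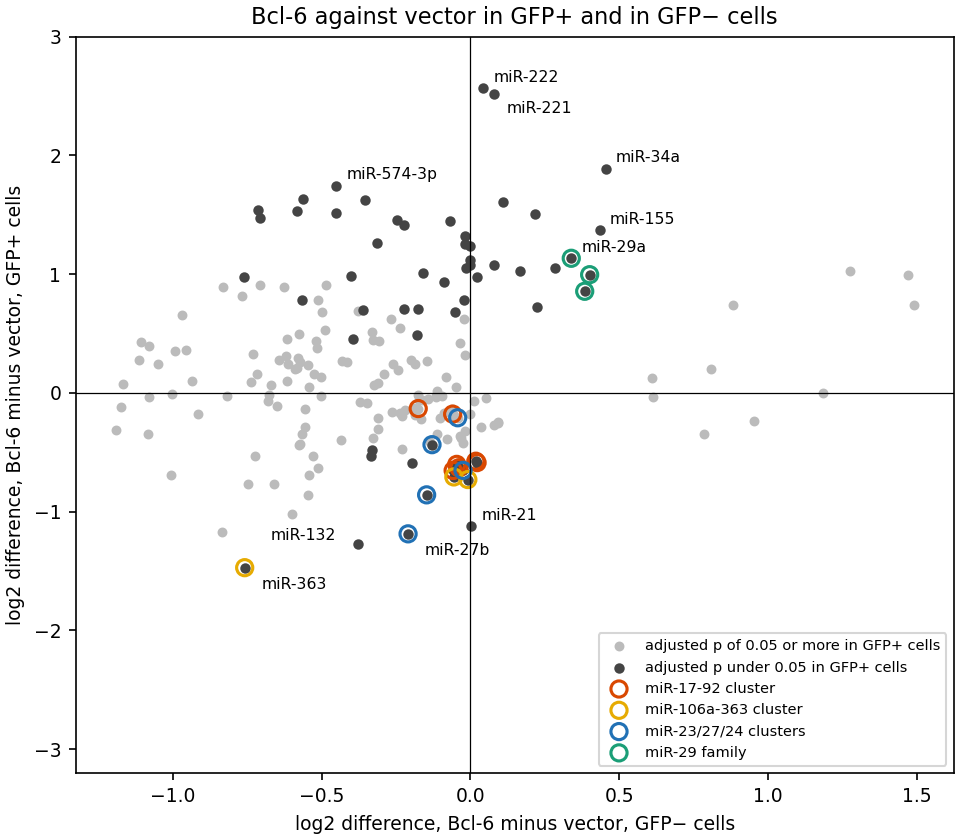
Log2 difference between Bcl-6 and vector in GFP-positive cells (vertical axis) against the same difference in GFP-negative cells (horizontal axis) for the 197 tested miRNAs; dark points passed in GFP-positive cells and rings mark 4 lists. miR-34a lies at 1.89 on the vertical and 0.45 on the horizontal axis and miR-21 at -1.12 and 0.00, while the numbers of rises and falls change with the scaling.

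Whether the difference between the Bcl-6 and vector cultures was unlike in the sorted fractions was tested as a difference of differences. miR-222 (2.52 ± 0.16, adjusted p = 0.000361), miR-221 (2.44 ± 0.23), miR-467b* (2.26 ± 0.55), miR-500 (2.20 ± 0.54) and miR-574-3p (2.20 ± 0.29) had the largest positive values. miR-714 (-1.13 ± 0.22), miR-21 (-1.13 ± 0.17), miR-132 (-0.90 ± 0.19), miR-20b (-0.72 ± 0.18) and miR-23b (-0.71 ± 0.19) had the lowest. Outside the Bcl-6 GFP-positive group, miR-222 was well above background on 1 and miR-221 on 2 of 6 arrays, so these values rest on dim signals. miR-467b* and miR-500 were well above background on 1 of the 2 Bcl-6 GFP-negative arrays, and without repeat 1 of that group, the array with uneven background, their values were 1.56 and 1.43. In all, 62 miRNAs passed in limma, 51 positive and 11 negative. The split was 27 positive and 33 negative with quantile normalization, 0 and 48 with no scaling, 10 and 30 with scaling on control RNAs and 2 and 13 on the corner spots. In camera the miR-17-92 (adjusted p = 0.000382), miR-23/27/24 (adjusted p = 0.00113), miR-106a-363 (adjusted p = 0.00843) and let-7 lists (adjusted p = 0.0363) were lower relative to the others. None held with an estimated correlation (adjusted p = 0.402 with an estimated correlation for the first 3 and 0.620 for let-7). Their members passing singly numbered 4, 2, 2 and 0, and adjusted over the list alone 5, 3, 2 and 0. The count was 2 without vector GFP-positive repeat 1 and 4 without its repeat 2, 23 without either Bcl-6 GFP-positive array, 37 without vector GFP-negative repeat 2 and 111 without Bcl-6 GFP-negative repeat 2. miR-221 and miR-222 were the 2 miRNAs that passed with each array left out in turn. miR-21 and miR-574-3p missed the threshold without either vector GFP-positive array (adjusted p up to 0.0599), and the other named miRNAs without any single one of the 4 GFP-positive arrays (adjusted p up to 0.139). miR-467b* and miR-500 also missed it without either vector GFP-negative array.

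The sorted fractions were also compared within the vector culture. In both cultures the GFP-negative arrays lay in slide columns 1 and 2 and the GFP-positive arrays in columns 3 and 4, so the sort and the slide column cannot be told apart in these comparisons. GFP-positive cells had higher miR-705 (1.02 ± 0.15, adjusted p = 0.0282), miR-451 (at least 1.99-fold, adjusted p = 0.0208) and miR-762 (at least 1.76-fold, adjusted p = 0.0280) than GFP-negative cells. These were the 3 miRNAs that passed, and 29 had an unadjusted p under 0.05. Of these 3, 0 passed with each array left out in turn. The count was 0 without vector GFP-negative repeat 2, without either vector GFP-positive array, without Bcl-6 GFP-positive repeat 2, and with no scaling, and 23 with scaling on control RNAs, of which 22 were lower. In camera the Sfmbt2 intron cluster was lower (median -0.54, adjusted p = 0.0154; adjusted p = 0.937 with an estimated correlation), with no member passing singly and 4 adjusted over the list alone. The miR-17-92 members had a median of 0.06 in this comparison.

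In the Bcl-6 culture, GFP-positive cells had higher miR-221 (2.54 ± 0.16), miR-705 (2.53 ± 0.15), miR-222 (2.52 ± 0.11), miR-680 (2.35 ± 0.29) and miR-451 (at least 2.54-fold) than GFP-negative cells. miR-221, miR-705, miR-222 and miR-680 were well above background on 1 of the 2 Bcl-6 GFP-negative arrays, so their values and order depend on the floor and on dim signals. miR-27b (-1.26 ± 0.22), miR-21 (-1.18 ± 0.12), miR-714 (-1.12 ± 0.15), miR-132 (-0.73 ± 0.13) and miR-27a (-0.72 ± 0.13) were lower. The adjusted p of these miRNAs ran from 4.02e-05 to 0.00626. Altogether 81 miRNAs passed, 65 higher and 16 lower. The split was 46 higher and 40 lower with quantile normalization, 5 and 95 with no scaling, 7 and 62 with scaling on control RNAs and 7 and 52 on the corner spots. In camera the miR-17-92 and miR-23/27/24 lists (adjusted p = 0.00189 for both) and miR-106a-363 (adjusted p = 0.0110) were lower, and none held with an estimated correlation (adjusted p = 0.481 with an estimated correlation for miR-17-92 and 0.429 for the others). Members passing singly numbered 5, 3 and 2, as they did adjusted over the list alone. This comparison shares the Bcl-6 GFP-positive arrays with the first, so the miRNAs that pass in both are not independent. The count was 122 without Bcl-6 GFP-negative repeat 2, and 52 and 50 without repeat 1 or repeat 2 of Bcl-6 GFP-positive cells.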

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

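The tests of scaling, of the sort, of the slide row, of signal that stays put and of the uneven array were chosen only after the result was seen.

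In the test of the difference of differences 62 miRNAs passed, a number that moved with the scaling and with single arrays, as given above. Those named by the rule were miR-222 (2.52 on the log2 scale), miR-221 (2.44), miR-467b* (2.26), miR-500 (2.20), miR-574-3p (2.20), miR-714 (-1.13), miR-21 (-1.13), miR-132 (-0.90), miR-20b (-0.72) and miR-23b (-0.71). Signal also appeared on probes for miRNAs of a mouse herpesvirus, which these cells are not known to carry. The 4 probes of mghv-miR-M1-2 were well above background on 7 of 8 arrays, with a mean processed signal of 35.1 over all arrays, and mghv-miR-M1-6 had a mean of 15.4, with at least 1 probe well above background on 6 of 8 arrays. The median of negative control spots was below 0.2 on every array but repeat 1 of Bcl-6 GFP-negative cells, where it was 14.1.

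The lower level of 15 members of the miR-17-92, miR-106a-363 and miR-23/27/24 lists in Bcl-6 GFP-positive cells was weighed against 4 technical explanations. The tables argue against the sort or vector, and against a slide row acting alike in all columns, as the whole cause. Dimming with scaling, and loss of signal that depends on brightness, stay open. These lists were picked for being lower than the other miRNAs on the same arrays, which enlarges their distance from other miRNAs. Arrays dimmed by 1 factor each, and scaling by such factors, would move all miRNAs alike. The members' median lay -0.57 from that of the 79 miRNAs seen on all arrays (-0.48 with quantile normalization). The SD between arrays of a typical single member was 0.083. This distance is no test of dimming, because the lists were picked as low on the same arrays. Loss of signal that depends on brightness would lower other miRNAs of like signal. Of 10000 lists matched on mean signal 0 had a median as low as the members' -0.63, and 95% of them lay from -0.25 to 0.70. This cannot decide the question, because the members were picked as low and the draws treat them as independent. Estimated correlations within the lists were 0.66, 0.38 and 0.53. The GFP sort, the slide column that goes with it, or the vector itself would lower the members in the vector culture too, where their median was 0.064, and a slide row would lower them in GFP-negative cells, where 13 of the 15 were below 0 but their median was -0.056, with miR-363 at -0.76 and the next lowest at -0.21. These comparisons cover a row in columns 1 and 2 and a column in row 1. Only the Bcl-6 GFP-positive arrays lay on row 2 in columns 3 and 4. An effect of that part of the slide cannot be told apart from the group and was not tested. A small part from the slide row is not excluded either. An effect of the Bcl-6 retrovirus remains open as a hypothesis. It was found and tested on the same 8 arrays, from what may be 1 RNA per group. Related miRNAs may also share signal.

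The 43 rises in Bcl-6 GFP-positive cells were weighed against signal that stays put while the array dims and is then lifted by the scaling. Their median unscaled log2 difference was 0.29, above the -0.53 of the control RNAs and below the 0.49 of the viral probes mghv-miR-M1-2. The explanation is thus not excluded for the median, and a rise in the cells stays open beside it. Scaling left these viral probes higher by 1.32 ± 0.36, against a median of 1.12 for the 43 miRNAs, while mghv-miR-M1-6, with at most 1 of its 4 probes above background on these arrays, differed by -0.046 ± 0.20 unscaled and 0.78 scaled, below the medians of the rises. The unscaled differences ran from -0.37 to 1.69, with 15 above that of mghv-miR-M1-2. Of these, 4 were above it by more than 0.36, namely miR-221 (1.69), miR-222 (1.57), miR-34a (1.06) and miR-574-3p (0.92). A smaller margin would take in more of the 15. These 4 were picked for their values, so their distance from these probes is no test, and whether they rose in the cells stays open.

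The absence of calls between the cultures in GFP-negative cells could come from the uneven background of 1 array, repeat 1 of Bcl-6 GFP-negative cells, if it hid changes. Without that array 0 miRNAs passed, which argues against it, although 1 array is then assumed to vary like the other groups. The 91 miRNAs that passed without repeat 2, of which 79 were lower, rested on the array with uneven background alone. Whether cells without visible GFP differ between the cultures stays open.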

How the results depend on the processing

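All alternatives were planned before the data were examined except array weights and scaling on the corner spots. Among the counts below, 89 alternatives stayed within 1.5 times the reported count and 61 did not. Unless stated, the cause of a change was not tested. The arrays of a group are few, and signal over background limits the dim miRNAs, of which 118 of 197 fell below background on at least 1 array. The 75th percentile over all mouse probes gave no scale, because it was -4.89 on repeat 1 of Bcl-6 GFP-negative cells, and a slide or scan block could not be fitted with 1 slide and 1 scan. Only the groups compared could not be fitted for the difference of differences.

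For Bcl-6 against vector in GFP-positive cells (60) the count was 165 with normexp, which also changed the input to median spot signals and added an offset, 33 with the total signal per miRNA and with the deposited table, which hold equal values, 117 with array weights, 24 on the corner spots, and 108 with only the groups compared. With the arrays averaged it was 2, in another contrast, that of Bcl-6 GFP-positive cells with the 3 other samples. Leaving out each array gave 27 to 103, the lone array of a group being assumed to vary like the other groups. In GFP-negative cells (0) it was 5 with normexp, 1 with quantile normalization, 6 with no scaling, 2 with only miRNAs seen on all arrays, 2 with a higher floor, 6 with trend and robust moderation, 6 on the corner spots, and 0 to 91 without each array. For the difference of differences (62) it was 154 with normexp, 40 on control RNAs, 29 with no filter, 13 with the total signal and with the deposited table, 25 with a lower floor, 15 on the corner spots, and 2 to 111 without each array.

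For the sort in the vector culture (3) the count was 23 with normexp, 5 with quantile normalization, 0 with no scaling, 23 on control RNAs, 9 with only miRNAs seen on all arrays, 1 with the mean over probes, 0 with the total signal and the deposited table, 1 with a lower floor, 0 with a higher floor, 11 with trend and robust moderation, 0 on the corner spots, 28 with only the groups compared, and 0 to 3 without each array. For the sort in the Bcl-6 culture (81) it was 171 with normexp, 44 with only miRNAs seen on all arrays, where 79 were tested, and 50 to 122 without each array. The 4 lists became 2 with only miRNAs seen on all arrays and 0 with an estimated correlation, and 3 to 6 without each array.

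Deviations of arrays with the same repeat number had correlations of -0.29 to 0.39 over 6 pairs of groups, with no common sign. The highest, 0.39, was that of vector and Bcl-6 GFP-positive cells, the groups of the first comparison. Whether the numbers pair the arrays there stays open. With the replicate block the count was 61 for GFP-positive cells, 0 for GFP-negative cells, 30 for the difference of differences, 0 for the sort in the vector culture and 76 in the Bcl-6 culture, with 4 lists.

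Of the miRNAs named, 8 turned sign under a setting while called on one side. Under normexp these were miR-363 (0.16), miR-181a (0.55), miR-195 (0.44) and miR-127 (0.52), without scaling miR-146a (-0.15), miR-669a (-0.046) and miR-297a (-0.12), and with quantile normalization miR-30d (-0.41). Among the other values of named miRNAs, 1538 stayed on their side of the threshold, 332 lost and 131 gained a call.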

Other observations

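The test of neighbouring miRNA genes was planned before its result was seen, and its repeats without 3 lists and without a repetitive group were added afterwards.

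Members of one genomic cluster are often cut from a shared primary transcript, which led to the hypothesis that neighbours change alike in Bcl-6 GFP-positive cells. Of the 197 tested miRNAs 188 (95.4%) matched a gene name in the mouse gene table of assembly GRCm38, giving 172 pairs of 77 miRNAs within 10 kb, pairs with the same family number left out. Neighbours differed by 0.54 on the log2 scale on average, against 0.78 after permuting values among miRNAs of like signal (permutation p = 0.00058, one-sided, 100000 permutations). Without pairs that hold a member of the miR-17-92, miR-106a-363 or miR-23/27/24 lists, 124 pairs differed by 0.61 against 0.79 (permutation p = 0.035). Of these pairs 92 lay inside the repetitive group of miR-297, miR-466, miR-467 and miR-669, which have related sequences. Without them and without the 3 lists, the remaining 32 pairs differed by 0.46 against 0.79 (permutation p = 0.0013). This is consistent with shared transcripts, but neighbours of related sequence may also share probes, which was not tested. Not all neighbours moved alike. In an example chosen after the values were seen, miR-132 differed by -1.27 and miR-212, from the same transcript, by -0.13, and miR-17 differed by -0.63 while the opposite strand of its hairpin, miR-17*, differed by -0.13.

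In the interaction test miR-714 had a negative value that arose mainly in GFP-negative cells, where Bcl-6 and vector differed by 0.79 ± 0.15 (adjusted p = 0.134), against -0.34 ± 0.15 in GFP-positive cells (adjusted p = 0.134).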
